A study of Homo sapiens with 15 samples.

How the data were processed

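Total RNA and ribosome footprints of MCF-10A cells were measured by sequencing in 15 libraries: total RNA after control siRNA (3) and eIF3e siRNA (3), footprints after control siRNA (3) and eIF3e siRNA (3), and 1 library each of total, eIF3B-bound and eIF3E-bound footprints. Per the labels, siRNA was used at 20 nM for 72 h. Lysates of 5 OD260 units were digested with 450 units of RNase I for 45 min, ribosomes were isolated on S-400 columns, footprints of 26 to 34 nt were taken from gels, and ribosomal RNA was removed with Ribo-Zero Gold.

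The deposited values are raw read counts per gene symbol. The submitters' processing notes list cutadapt 1.18, Bowtie 1.1.2, STAR 2.5 and HTSeq with the builds hg38 and GRCh38. The role and order of these tools, the annotation, the strand setting and the counted feature are not given in the sources used here. The total RNA table held 56475 symbols, of which 35359 matched a current RefSeq symbol, 1449 an older one and 19667 none, and 27334 had a count. The footprint table held 20248 symbols (18891, 779 and 578), all of them also in the total RNA table, of which 13152 had a count in the siRNA libraries and 11971 in the single libraries. Genes are named as the tables name them. All columns of per-sample values were mapped to samples from their titles (0 unmapped).

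Depth was 4263767 to 5646270 counts per total RNA library, 1889543 to 3447360 per siRNA footprint library and 1224606 to 1630872 per single library. Floors are 3 counts of the library total, and intervals are exact at 95%. The share of total RNA counts on genes of the footprint table was 64.0 to 76.8%. The replicate variation (biological coefficient of variation of edgeR) was 0.155 in total RNA and 0.245 in footprints.

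Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr with a minimum count of 10, TMM factors within each assay, robust quasi-likelihood fit and F test, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Total RNA and footprints were fitted apart, on 6 libraries each, with the siRNA as the only term. Footprints per mRNA were tested as the interaction of assay and siRNA in one fit over the 12 libraries, on genes passing the filter in both assays. The change in footprints was compared with that in total RNA across genes by Pearson's r, Spearman's rho and total least squares slope, with jackknife errors from leaving out each treatment and number in turn.

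Before the data were examined, 37 gene lists were fixed: translation machinery, mitochondrial, secretory and stress genes, cell cycle and DNA damage, markers of cell type, interferon and inflammatory genes, and metabolism. Lists with at least 5 tested members (36) were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry. The tests, groups and the naming rule were fixed at the same time. The rule names EIF3E, each eIF3 subunit, and per comparison the 10 genes higher and 10 lower with the largest change among those called, with a mean count of at least 50, and in total RNA and footprints with all 3 eIF3e siRNA libraries on one side of all 3 control libraries. It adds up to 4 called members per list with the smallest adjusted p, or the 2 most abundant where none was called. Some genes that these rules name are not reported here. For the single libraries no rule was fixed: genes with at least 100 counts in 1 of the 3 libraries were scaled by TMM factors against the total library (0.972 and 0.976), and genes with both intervals on one side of 0 were ranked by the weaker of their ratios, of which the first 10 in each direction gave the names, chosen after the values were seen. Exact conditional intervals were used for ratios. List medians were set beside 10000 random lists of the same size, matched on the summed counts of the 3 libraries.

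Alternatives tried were DESeq2 1.42.0 size factors, total-count scaling, TMM over all 12 libraries, no filter and a minimum count of 50, the DESeq2 Wald test, limma-voom with sample weights, the replicate number or the treatment and number as a block, 1 fit over all 12 libraries, leaving out mitochondrially encoded genes, and leaving out each replicate. A term for the 7SL level, restriction to genes of the footprint table, scaling and a minimum count of 200 in the single libraries, leave-one-out values of the correlation, total-count scaling with libraries left out and the eIF3 list without EIF3E were added after the data were seen.

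The calls were tested on simulated data in which 200 genes were changed among replicates drawn with the spread fitted in each comparison. For footprints per mRNA this was 1 spread for both assays (biological coefficient of variation 0.153), below the 0.245 of footprints alone. The shares given for footprints per mRNA may therefore not hold for the measured libraries. Of genes changed 1.5-fold, 2-fold and 4-fold, 17.9, 77.6 and 93.9% were recovered in total RNA, 14.9, 38.8 and 72.7% in footprints, and 8.96, 38.8 and 89.4% in footprints per mRNA. Unchanged genes made up 2.31, 3.23 and 6.19% of calls, and 0 of 20 unchanged lists was called in each. The simulated genes were drawn independently. The list result therefore does not cover lists whose genes move together, such as ribosomal proteins (estimated correlation 0.64 in total RNA). Reads, codon positions and the 5' and 3' untranslated regions were not analysed here, since the tables give 1 count per gene.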

Results

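MCF-10A cells, a non-tumorigenic human mammary epithelial line, were treated for 72 h with 20 nM siRNA against eIF3e or with control siRNA. eIF3e is a subunit of eIF3, the initiation complex that binds the small ribosomal subunit and brings it to mRNAs. The question is which mRNAs, and which ribosome footprints, differ once eIF3e is depleted. Total RNA and ribosome-protected footprints of 26 to 34 nt were each sequenced from 3 libraries per siRNA, which makes 12 of the 15 libraries. The other 3 libraries are footprints from MCF-10A lysate, from ribosomes bound by eIF3B and from ribosomes bound by eIF3E, with 1 library each and no siRNA named for these cells.

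The 6 total RNA libraries held 4263767 to 5646270 counts, the 6 siRNA footprint libraries 1889543 to 3447360. The total, eIF3B-bound and eIF3E-bound footprint libraries held 1224606, 1433096 and 1630872 counts. A count of 0 allows up to 0.531 to 0.704 CPM (counts scaled to the library total) in a total RNA library, 0.870 to 1.59 CPM in a siRNA footprint library and 1.84 to 2.45 CPM in a single library. These floors, and the intervals given with single libraries, cover counting error only. In total RNA the most abundant gene was RPPH1, the RNA of ribonuclease P, at 9.33 to 12.3% of counts in the control libraries and 6.37 to 7.10% after eIF3e siRNA. Genes of the footprint table held 64.0 to 71.2% of total RNA counts in control and 73.1 to 76.8% after eIF3e siRNA, so the composition of total RNA differed with the siRNA. RN7SL1 and RN7SL2, the 7SL RNAs of the signal recognition particle, together took 4.36, 3.91 and 2.44% in the control libraries and 1.02, 4.07 and 0.126% in the eIF3e siRNA libraries. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these libraries. Changes are log2 fold changes, eIF3e siRNA over control, ± SE with n = 3 per group.

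EIF3E, the target of the siRNA, lies on chromosome 8 (GRCh38.p14, 108201216 to 108248717, protein-coding). Its levels are given as TMM-scaled CPM, with library totals multiplied by their TMM factors. In total RNA it was at 198, 219 and 188 CPM in the control libraries and at 20.6, 21.4 and 25.9 CPM in the eIF3e siRNA libraries. Its mRNA fell by 3.15 ± 0.12 (log2, edgeR adjusted p = 1.6e-10), to 11.2% of control. EIF3E footprints were at 423, 393 and 387 CPM in the control libraries and at 57.4, 40.6 and 64.2 CPM after eIF3e siRNA. They fell by 2.88 ± 0.16 (edgeR adjusted p = 5.3e-14), to 13.5% of control. Footprints per mRNA of EIF3E did not pass the test (0.26 ± 0.20, edgeR adjusted p = 0.67).

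**Figure D1:**
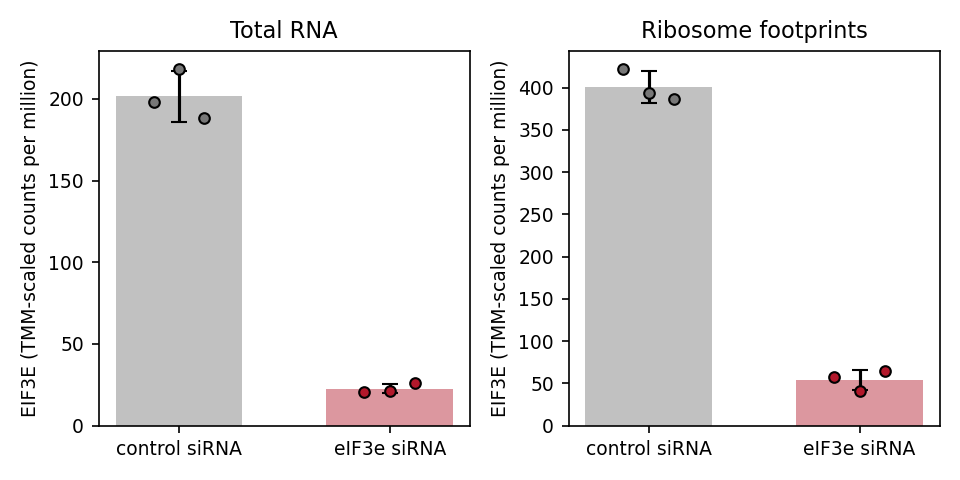
EIF3E in TMM-scaled CPM (linear axes from 0) in total RNA and in ribosome footprints, one point per library, with the mean and SD of each group of 3. In both assays all 3 eIF3e siRNA libraries lie below all 3 control libraries, at 20.6 to 25.9 against 188 to 219 CPM in total RNA and 40.6 to 64.2 against 387 to 423 CPM in footprints.

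Other eIF3 subunits were lower as well. In total RNA 1 of 12 tested members rose and 7 fell (1 and 7 adjusted over the list alone), EIF3E included. EIF3L was at −1.26 ± 0.10, EIF3H at −0.72 ± 0.10 and EIF3I at −0.70 ± 0.13. As a list the subunits were lower (camera adjusted p = 0.00015, and adjusted p = 0.31 with an estimated correlation), and without EIF3E, the target, the other 11 had camera adjusted p = 0.017, and adjusted p = 0.51 with an estimated correlation. In footprints 6 of 12 fell and 0 rose (1 and 8 adjusted over the list alone), with EIF3M at −0.86 ± 0.14, EIF3L at −0.76 ± 0.14 and EIF3H at −0.75 ± 0.13. The list had camera adjusted p = 4.7e-07, and adjusted p = 0.079 with an estimated correlation, and without EIF3E it had camera adjusted p = 0.0012, and adjusted p = 0.12 with an estimated correlation. In footprints per mRNA no subunit was called (1 and 1 adjusted over the list alone), and the list was not (camera adjusted p = 0.69). EIF3C and its near-identical copy EIF3CL had 0 total RNA counts and 30 and 0 footprint counts over the 6 siRNA libraries of each assay, so nothing can be said of them.

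In total RNA, genes of squamous differentiation fell and interferon-stimulated genes rose. KLK7 (−2.42 ± 0.12), KLK5 (−2.18 ± 0.11) and KLK8 (−1.90 ± 0.12), kallikrein proteases of stratified epithelium, were among the largest decreases. So were SCEL, a precursor of the cornified envelope (−2.05 ± 0.14), and CRABP2, which carries retinoic acid (−2.19 ± 0.14). FRMD3 (−2.26 ± 0.16), FAM171B (−2.14 ± 0.16), the nuclear receptor gene RORA (−2.09 ± 0.30) and HERPUD1, an endoplasmic reticulum (ER) stress gene of protein degradation (−1.77 ± 0.12), completed the 10 largest with EIF3E. Among the largest increases were the interferon-stimulated genes RSAD2 (2.63 ± 0.31) and ISG15 (2.49 ± 0.14), with FJX1 (2.52 ± 0.19) and the non-coding HCP5 (2.44 ± 0.20). The naming rule requires that all of these lie outside the control range in every eIF3e siRNA library.

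The largest fitted increases were of another kind. PROC (5.86 ± 1.33), DUXB (4.77 ± 0.59), PLAC4 (4.49 ± 0.82), LINC01184 (3.25 ± 0.79) and RN7SL305P (2.97 ± 0.72) had edgeR adjusted p from 0.0034 to 0.038. Over the 6 siRNA footprint libraries PROC and DUXB had 0 counts, and the other 3 are not in that table. RN7SL305P is a pseudogene of 7SL RNA. Of 260 such pseudogenes tested, 29 rose and 13 fell. PROC had 0 counts in control libraries 1 and 2 and 8 in control library 3, so its fold rests on that library and none is given without it. The call of DUXB held without any 1 library. The calls of PROC, PLAC4, LINC01184 and RN7SL305P were lost without control library 1 or without eIF3e siRNA library 1. They were also lost without control library 2 or 3 (PROC and LINC01184), control library 2 (RN7SL305P), eIF3e siRNA library 2 (RN7SL305P) or 3 (PROC, PLAC4 and RN7SL305P). The highest edgeR adjusted p over the alternatives was 0.14 for PROC, 0.071 for PLAC4, 0.13 for LINC01184 and 0.11 for RN7SL305P.

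Across total RNA, 2202 genes rose and 2197 fell of 11719 tested (edgeR, Benjamini-Hochberg adjusted p under 0.05), of which 658 and 364 changed at least 2-fold. At an unadjusted p under 0.05 there were 5490 genes where 586 would be expected by chance. The groups did not overlap in 49.7% of genes, against 10% by chance. The balance of directions depended on scaling. With total counts in place of TMM factors the median of all genes moved by 0.16 (log2) and 70.6% of the called genes were higher, against 50.1%.

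Interferon-stimulated genes rose most as a group in total RNA: 23 of 29 tested members rose and 0 fell (23 and 0 adjusted over the list alone). Examples are IFI6 (2.34 ± 0.11), BST2 or tetherin (2.21 ± 0.10) and OAS2, a sensor of double-stranded RNA (2.44 ± 0.14). Their median was 0.90 (camera adjusted p = 3.5e-18, and adjusted p = 0.25 with an estimated correlation). Of the squamous differentiation genes 0 of 15 tested members rose and 11 fell (1 and 11 adjusted over the list alone), with the cornified envelope gene SPRR1B at −1.29 ± 0.18 and S100A9 at −0.77 ± 0.12. Their median was −0.86 (camera adjusted p = 5.8e-07, and adjusted p = 0.13 with an estimated correlation). Of the mesenchymal genes 10 of 18 tested members rose and 1 fell (10 and 1 adjusted over the list alone). TNC, or tenascin C (1.90 ± 0.12), THBS1, or thrombospondin 1 (1.37 ± 0.10), and FN1, or fibronectin (1.33 ± 0.11), were among the clearest (camera adjusted p = 0.00030, and adjusted p = 0.13 with an estimated correlation). The matrix adhesion genes were not called as a list in total RNA, where 10 of 29 tested members rose and 5 fell (11 and 5 adjusted over the list alone), at camera adjusted p = 0.28. Of the epithelial junction genes 4 of 29 tested members rose and 15 fell (4 and 15 adjusted over the list alone), among them DSC2 (−0.95 ± 0.10) and OCLN (−0.74 ± 0.12), a desmosomal and a tight junction protein (camera adjusted p = 0.013, and adjusted p = 0.31 with an estimated correlation). Of 3 tested markers of fibroblasts, endothelium and blood, DCN (0.73 ± 0.13) and CD14 (0.57 ± 0.17) rose, too few for a list test. Without any 1 library other than control library 3 the CD14 call was lost (highest edgeR adjusted p = 0.11).

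Nuclear genes of mitochondrial import, of the mitochondrial ribosome and of complex I, and DNA replication genes, rose in total RNA. Among mitochondrial import genes 15 of 29 tested members rose and 2 fell (17 and 2 adjusted over the list alone), with the import motor HSPA9 at 1.00 ± 0.10 and TIMM50 at 1.15 ± 0.13 (camera adjusted p = 9.2e-05, and adjusted p = 0.31 with an estimated correlation). Among mitochondrial ribosomal proteins 24 of 75 tested members rose and 1 fell (24 and 1 adjusted over the list alone), with MRPS22 at 1.14 ± 0.16 and MRPL4 at 1.09 ± 0.16 (camera adjusted p = 0.0025, and adjusted p = 0.13 with an estimated correlation). Among complex I subunits 11 of 36 tested members rose and 0 fell (10 and 0 adjusted over the list alone), with NDUFS8 at 0.91 ± 0.11 (camera adjusted p = 0.015, and adjusted p = 0.45 with an estimated correlation), and without control library 3 this list had camera adjusted p = 0.051. Of the DNA replication genes 13 of 29 tested members rose and 1 fell (13 and 1 adjusted over the list alone), with the helicase subunits MCM2 at 1.27 ± 0.17 and MCM3 at 1.23 ± 0.20 (camera adjusted p = 0.0014, and adjusted p = 0.13 with an estimated correlation). Other mitochondrial lists were not called in total RNA. Of the subunits of complexes II, III and IV 6 of 26 tested members rose and 2 fell (6 and 2 adjusted over the list alone), at camera adjusted p = 0.65. Of the ATP synthase subunits 3 of 16 tested members rose and 2 fell (3 and 2 adjusted over the list alone), at camera adjusted p = 0.72, and of the tricarboxylic acid cycle genes 8 of 22 tested members rose and 4 fell (10 and 4 adjusted over the list alone), at camera adjusted p = 0.42.

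Messenger RNAs of ribosomal proteins and initiation factors fell, and so did those of antioxidant, autophagy and heat shock genes. Of the cytosolic ribosomal protein genes 1 of 79 tested members rose and 31 fell (3 and 36 adjusted over the list alone), with a median of −0.45 (camera adjusted p = 4.0e-06, and adjusted p = 0.71 with an estimated correlation). Examples are RPL22 (−1.15 ± 0.13), RPL3 (−1.13 ± 0.13) and RPLP0 (−1.26 ± 0.16). Many of these genes have processed pseudogenes that can share reads. The 7SL share of total RNA differed between libraries, at 2.44 to 4.36% in control and 0.126 to 4.07% after eIF3e siRNA, and with the 7SL level as a term the median was −0.27. With total-count scaling it was −0.28, and the list was still called. Of the other initiation factors 2 of 33 tested members rose and 12 fell (2 and 13 adjusted over the list alone), with the poly(A)-binding protein PABPC1 at −1.23 ± 0.12, the eIF2 subunit EIF2S3 at −1.01 ± 0.11 and the helicase DDX3X at −0.97 ± 0.11 (camera adjusted p = 0.015, and adjusted p = 0.45 with an estimated correlation). The initiation factor median was −0.18, close in size to the 0.16 by which total-count scaling raised the median of all genes. The initiation list was still called with that scaling. Of the elongation and termination factors 3 of 14 tested members rose and 5 fell (3 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.42). Of the NRF2 and antioxidant genes 2 of 22 tested members rose and 8 fell (2 and 8 adjusted over the list alone), with glutathione reductase GSR at −0.90 ± 0.10 and AKR1B10 at −1.16 ± 0.13 (camera adjusted p = 0.0048, and adjusted p = 0.36 with an estimated correlation). Of the autophagy genes 0 of 25 tested members rose and 9 fell (0 and 9 adjusted over the list alone), with the receptor OPTN at −0.95 ± 0.11 (camera adjusted p = 0.023, and adjusted p = 0.45 with an estimated correlation). Of the cytosolic heat shock genes 1 of 21 tested members rose and 11 fell (1 and 11 adjusted over the list alone), with the chaperonin subunits CCT8 (−0.60 ± 0.11) and TCP1 (−0.64 ± 0.12), at camera adjusted p = 0.023, and adjusted p = 0.55 with an estimated correlation. Without eIF3e siRNA library 1 the heat shock list had camera adjusted p = 0.059, with a stricter count filter 0.064, and with the 7SL level as a term 0.074.

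In footprints PNPT1, a mitochondrial polynucleotide phosphorylase and interferon target, rose by 2.92 ± 0.19. RSAD2 (2.89 ± 0.37), ISG15 (2.83 ± 0.17) and BST2 (2.43 ± 0.14) rose, and so did the zinc transporter SLC39A8 (2.69 ± 0.19), the activin subunit INHBA (2.47 ± 0.27) and the aldehyde oxidase AOX1 (2.45 ± 0.40). The gap junction gene GJA1 (2.39 ± 0.26), the protease inhibitor SERPINE2 (2.36 ± 0.21) and the collagen COL8A1 (2.34 ± 0.23) complete the 10 largest increases. The largest decreases after EIF3E were KLK6 (−2.59 ± 0.37), SCEL (−2.17 ± 0.16), KLK7 (−2.11 ± 0.14), CRABP2 (−2.01 ± 0.17) and IL1RN, the interleukin 1 receptor antagonist (−1.99 ± 0.32). HPS5 (−1.92 ± 0.18), the motor MYO5B (−1.91 ± 0.29), FRMD3 (−1.91 ± 0.29) and KLK8 (−1.89 ± 0.15) followed. Of 9228 genes tested, 926 rose and 781 fell (edgeR, adjusted p under 0.05), 391 and 277 at least 2-fold. There were 2754 genes at an unadjusted p under 0.05, with 461 expected by chance, and the groups did not overlap in 33.7% of genes, against 10% by chance.

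Squamous differentiation genes fell furthest as a group in footprints. There 1 of 15 tested members rose and 10 fell (1 and 12 adjusted over the list alone), with a median of −1.22. KLK5 was at −1.55 ± 0.13, the keratin KRT16 at −1.32 ± 0.15 and the protease inhibitor CSTA at −1.22 ± 0.15. This list (camera adjusted p = 5.9e-13, and adjusted p = 0.044 with an estimated correlation) was the only one of the lists called in any comparison that held with an estimated correlation. Of the interferon-stimulated genes 11 of 30 tested members rose and 1 fell (13 and 1 adjusted over the list alone), with IFI6 at 2.16 ± 0.12 and IFI27 at 1.49 ± 0.12 (camera adjusted p = 5.9e-13, and adjusted p = 0.12 with an estimated correlation). Of the mesenchymal genes 5 of 17 tested members rose and 1 fell (5 and 1 adjusted over the list alone). FN1 rose by 1.75 ± 0.13 and TNC by 1.94 ± 0.16, while the median of the list was 0.07 (camera adjusted p = 0.00021, and adjusted p = 0.27 with an estimated correlation). That median was 0.30 without control library 1, 0.31 without control library 3 and 0.26 without eIF3e siRNA library 1. Of the matrix adhesion genes 12 of 29 tested members rose and 2 fell (12 and 3 adjusted over the list alone), with the integrins ITGA5 at 1.53 ± 0.12 and ITGA3 at 1.07 ± 0.11 (camera adjusted p = 0.0018, and adjusted p = 0.34 with an estimated correlation). Of the epithelial junction genes 2 of 30 tested members rose and 10 fell (3 and 11 adjusted over the list alone), with OCLN at −0.89 ± 0.14 and plakoglobin, JUP, at −0.65 ± 0.12 (camera adjusted p = 0.010, and adjusted p = 0.40 with an estimated correlation). Of the luminal mammary markers 1 of 11 tested members rose and 5 fell (1 and 7 adjusted over the list alone), with the keratins KRT18 at −0.58 ± 0.14 and KRT7 at −0.47 ± 0.11 (camera adjusted p = 0.010, and adjusted p = 0.21 with an estimated correlation). With a stricter count filter the luminal list had camera adjusted p = 0.098. DCN (1.05 ± 0.17) and CD14 (0.94 ± 0.15), of 3 tested markers of other cell types, rose.

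Footprints of nuclear respiratory genes rose. Of the complex I subunits 10 of 36 tested members rose and 1 fell (10 and 1 adjusted over the list alone), with NDUFS8 at 1.19 ± 0.14 (camera adjusted p = 0.00073, and adjusted p = 0.10 with an estimated correlation). Of the subunits of complexes II, III and IV 7 of 25 tested members rose and 2 fell (9 and 2 adjusted over the list alone), with succinate dehydrogenase SDHA at 1.40 ± 0.13 (camera adjusted p = 0.010, and adjusted p = 0.34 with an estimated correlation). Of the ATP synthase subunits 6 of 16 tested members rose and 0 fell (6 and 0 adjusted over the list alone), with ATP5B at 0.90 ± 0.11 (camera adjusted p = 0.016, and adjusted p = 0.50 with an estimated correlation, and 0.054 without control library 1). Mitochondrial import genes (7 of 26 higher and 0 lower, 9 and 0 adjusted over the list alone, PMPCA 1.03 ± 0.13) rose as a list (camera adjusted p = 0.0012, and adjusted p = 0.11 with an estimated correlation). So did mitochondrial ribosomal proteins (14 of 74 higher and 0 lower, 14 and 0 adjusted over the list alone, MRPL32 1.05 ± 0.16), at camera adjusted p = 0.014, and adjusted p = 0.34 with an estimated correlation, and camera adjusted p = 0.052 with a stricter count filter. Of the ER chaperones 9 of 19 tested members rose and 2 fell (10 and 3 adjusted over the list alone), with the disulfide isomerases PDIA3 at 0.96 ± 0.11 and PDIA4 at 0.85 ± 0.12, and HERPUD1 at −1.58 ± 0.17 (camera adjusted p = 0.0065, and adjusted p = 0.55 with an estimated correlation). Of the lysosomal genes 7 of 30 tested members rose and 3 fell (11 and 4 adjusted over the list alone), with the protease CTSC at 1.14 ± 0.11 and the galactosidase GLA at 1.29 ± 0.16 (camera adjusted p = 0.016, and adjusted p = 0.55 with an estimated correlation). Without control library 3 the ER chaperone and lysosome lists had camera adjusted p = 0.060 and 0.093, and with a stricter count filter the lysosome list had 0.093.

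Footprints on antioxidant, elongation factor, ribosomal protein, heat shock and glycolysis mRNAs fell. Of the NRF2 and antioxidant genes 0 of 21 tested members rose and 12 fell (0 and 14 adjusted over the list alone), with the pentose phosphate enzyme PGD at −0.97 ± 0.15 and the quinone reductase NQO1 at −0.88 ± 0.15 (camera adjusted p = 2.4e-05, and adjusted p = 0.10 with an estimated correlation). Of the elongation and termination factors 0 of 15 tested members rose and 5 fell (0 and 5 adjusted over the list alone), with EEF2, which moves the ribosome along the mRNA, at −1.21 ± 0.11 (camera adjusted p = 0.0051, and adjusted p = 0.34 with an estimated correlation). Of the ribosomal proteins 4 of 68 tested members rose and 14 fell (4 and 18 adjusted over the list alone), with RPL5 at −1.11 ± 0.14 and RPL3 at −0.92 ± 0.13 (camera adjusted p = 0.0071, and adjusted p = 0.60 with an estimated correlation, and 0.071 without eIF3e siRNA library 1). Of the heat shock genes 0 of 21 tested members rose and 7 fell (0 and 8 adjusted over the list alone), with HSPB1 at −1.04 ± 0.13 (camera adjusted p = 0.0021, and adjusted p = 0.34 with an estimated correlation). Of the glycolysis genes 2 of 16 tested members rose and 5 fell (2 and 7 adjusted over the list alone), with pyruvate kinase PKM at −0.88 ± 0.11 and LDHB at −0.78 ± 0.12 (camera adjusted p = 0.013, and adjusted p = 0.27 with an estimated correlation). Of the other initiation factors 1 of 32 tested members rose and 6 fell (1 and 6 adjusted over the list alone), and as a list they did not pass (camera adjusted p = 0.073).

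In all, camera called 6 lists higher and 8 lower in total RNA and 10 higher and 9 lower in footprints, of 36 tested. With an estimated correlation 0 lists held in total RNA (5 at an unadjusted p under 0.05) and 1 in footprints. Among called lists in total RNA the estimate was above the preset 0.01 for some, such as ribosomal proteins (0.64) and interferon-stimulated genes (0.35). It was below 0.01 for others, such as squamous differentiation (−0.0067), mesenchymal (−0.021) and replication genes (−0.011). For those lists, genes that move together do not account for the lost call. The second test, fry, which asks whether the genes of a list move one way on balance, called 20 lists in total RNA, 18 in footprints and 0 in footprints per mRNA (2 at an unadjusted p under 0.05).

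**Figure D2:**
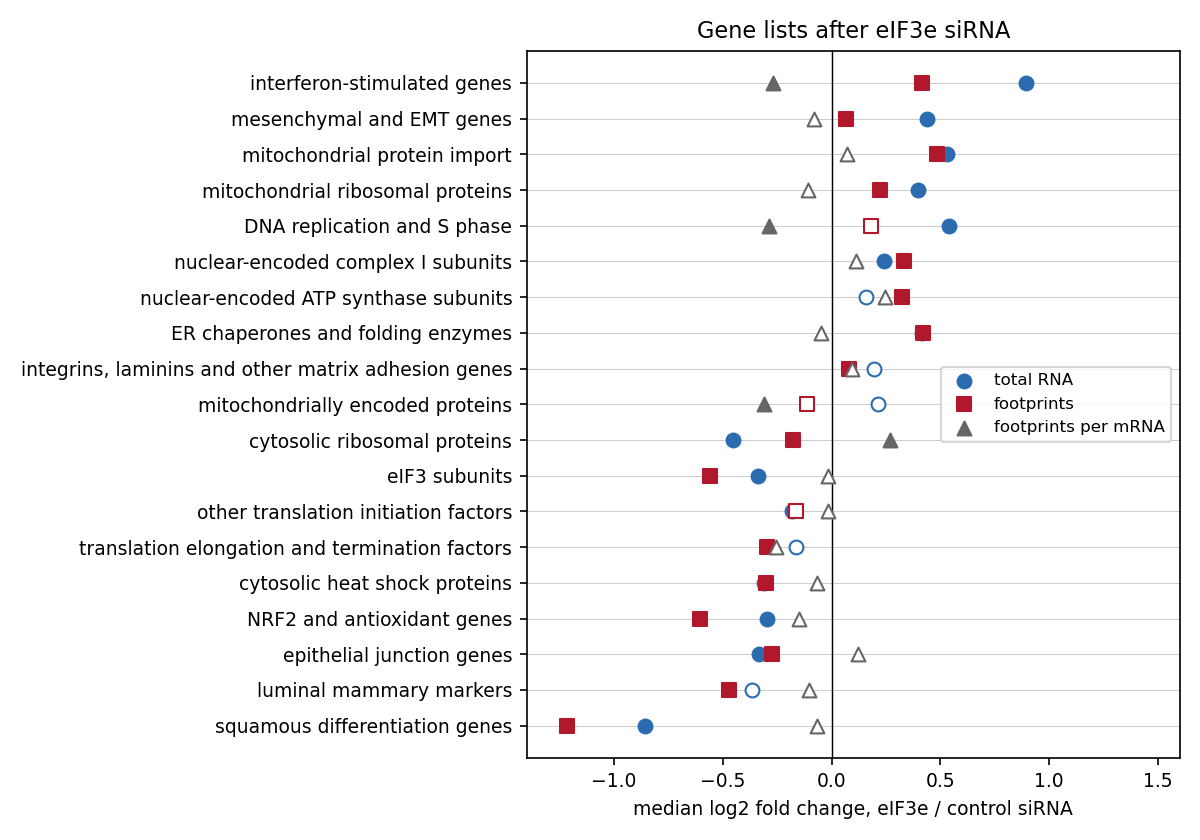
Median log2 fold change (eIF3e siRNA over control, n = 3 per group) of the gene lists shown in total RNA, in footprints and in footprints per mRNA, with filled symbols for lists called by camera. Squamous differentiation genes have the lowest medians, −0.86 in total RNA and −1.22 in footprints, and interferon-stimulated genes are at 0.90 and 0.42 (0.27 in footprints without eIF3e siRNA library 2).

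Most genes called in footprints moved the same way in total RNA. ISG15, BST2, TNC and FN1 rose in both, and KLK5, KLK7, SCEL and CRABP2 fell in both. Of 1697 genes called in footprints and tested in both assays, 1631 (96.1%) had the same sign in total RNA and 1317 were called there too. Both assays called 713 genes higher and 604 lower, where 188 and 166 would be shared if the calls were independent, and 5 genes were called in opposite directions. These were HIST1H1E, lower in footprints, and LINC00493, NIPAL4, REEP3 and TMEM30B, higher in footprints, named for this after their values were seen. Across 9055 genes, which are not independent replicates, Pearson's r was 0.67 ± 0.06 (jackknife SE), Spearman's rho 0.64 ± 0.05 and the total least squares slope 1.31 ± 0.26, footprints on total RNA. With a stricter count filter r was 0.80 and the slope 1.105. The median SE of the changes was larger in footprints (0.327) than in total RNA (0.175), so the slope alone cannot show larger changes in footprints.

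**Figure D3:**
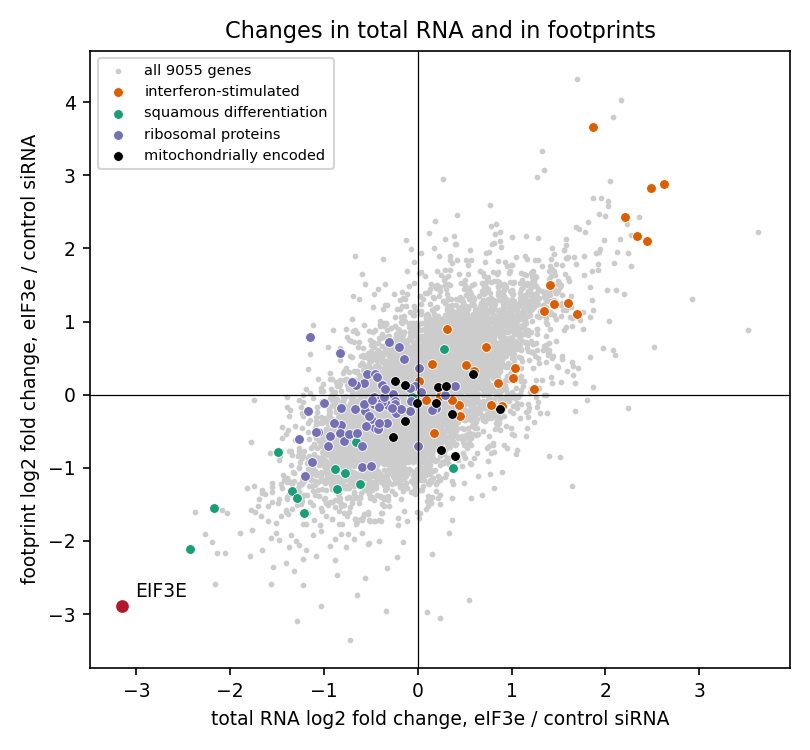
Log2 fold change after eIF3e siRNA in footprints (y axis) against total RNA (x axis), one point per gene tested in both assays (9055 genes, n = 3 libraries per group and assay), with members of 4 gene lists coloured and EIF3E labelled. Most called genes lie in the quadrants of equal sign: 713 were called higher and 604 lower in both assays, and 5 in opposite directions.

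Footprints per mRNA compare the footprint change with the mRNA change of the same gene. They ask whether an mRNA gained or lost ribosomes beyond its abundance, relative to other genes. Scaling within each assay puts the median change near 0 (−0.002), so a gain or loss shared by all mRNAs cannot be seen. Few genes passed: 7 rose and 15 fell of 9060 tested (edgeR interaction test, adjusted p under 0.05), 3 and 12 at least 2-fold, with 1082 genes at an unadjusted p under 0.05 where 453 would be expected. The initiation factor EIF4B rose by 1.67 ± 0.34 and PABPC1 by 0.97 ± 0.17: their mRNAs fell (−1.75 and −1.23) while their footprints were at −0.07 and −0.25 and not called. The ribosomal stalk protein RPLP1 (1.01 ± 0.21), the lipid flippase subunit TMEM30B (1.13 ± 0.23), MAL2 (0.89 ± 0.17), TMEM123 (0.88 ± 0.15) and REEP3 (0.87 ± 0.17) rose as well. The linker histone gene HIST1H1E fell by 1.46 ± 0.24, with more mRNA (0.80) and fewer footprints (−0.66). The transcription regulator ID1 (−1.07 ± 0.17), the metallothionein MT2A (−1.20 ± 0.21), the myosin light chain MYL6 (−1.08 ± 0.22), the actin-binding TMSB10 (−1.03 ± 0.20), ARHGDIA and the interferon-induced IFIT1 (−1.06 ± 0.22) fell, as did MT-ND6 (−1.26 ± 0.22), MT-ND1 (−1.09 ± 0.20) and MT-ND4 (−1.01 ± 0.17). The edgeR adjusted p values of these 17 genes ran from 0.014 to 0.045. The other 5 called lower, KRT81, SFN, GLI3, MSL1 and RNF4, fall outside the naming rule and were named after their values were seen.

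The number of calls depended on the libraries used. Without control replicate 2, or without eIF3e siRNA replicate 1 or 3, edgeR called 0 genes, with 996, 951 and 983 at an unadjusted p under 0.05. It called 1 higher and 1 lower without control replicate 1, 2 and 7 without eIF3e siRNA replicate 2, and 7 and 14 without control replicate 3, with 14 of the 22 calls shared. With the 7SL level as a term it called 0 (792 at an unadjusted p under 0.05), while the DESeq2 Wald test on all libraries called 76 higher and 66 lower. With TMM over all 12 libraries edgeR called 26 higher and 15 lower, so the balance of directions depended on scaling too. With treatment and number as a block, as if equal numbers of both assays shared a culture, it called 82 higher and 64 lower. Replicate number as a block gave 2 and 4. The labels do not say whether equal numbers share a culture.

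In footprints per mRNA camera called the ribosomal protein list higher and the mitochondrially encoded, interferon and replication lists lower, with few single members called. None of these calls held with an estimated correlation, and fry called 0 lists (2 at an unadjusted p under 0.05). For ribosomal proteins the median was 0.27, 1 of 68 tested members rose and 0 fell (12 and 1 adjusted over the list alone), and the list had camera adjusted p = 2.7e-06, and adjusted p = 0.77 with an estimated correlation. With the 7SL level as a term the median was 0.08 (camera adjusted p = 0.20). For the mitochondrially encoded genes the median was −0.31, 0 of 13 tested members rose and 3 fell (0 and 4 adjusted over the list alone), at camera adjusted p = 1.3e-05, and adjusted p = 0.77 with an estimated correlation. Without control replicate 2 that median was −0.12, and the list was still called. In total RNA 4 of 13 tested members rose and 1 fell (4 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.42). In footprints 0 of 13 tested members rose and 4 fell (0 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.074). MT-ND1 rose in total RNA (0.88 ± 0.14), and MT-ND4 (−0.75 ± 0.12), MT-ND6 (−0.84 ± 0.14) and MT-CO3 (−0.58 ± 0.12) fell in footprints. MT-ND6 adjoins MT-ND5 on the other strand, and MT-ATP8 and MT-ND4L overlap MT-ATP6 and MT-ND4. The counts of these genes are uncertain without the strand setting and the counted feature.

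For the interferon-stimulated genes the median was −0.27, 0 of 29 tested members rose and 1 fell (0 and 8 adjusted over the list alone), at camera adjusted p = 0.00016, and adjusted p = 0.77 with an estimated correlation. IFIT1 mRNA rose (0.90) while its footprints were at −0.15 and not called. The DNA replication genes had a median of −0.29, 0 of 26 tested members rose and 0 fell (0 and 2 adjusted over the list alone), at camera adjusted p = 0.013, and adjusted p = 0.77 with an estimated correlation. Their footprints were not called as a list (0 of 27 higher and 0 lower, 0 and 0 adjusted over the list alone, camera adjusted p = 0.83). Without control replicate 2 the median was −0.45. The replication call was lost without control replicate 3, where the median was −0.06 (camera adjusted p = 0.40), without eIF3e siRNA replicate 2 or 3 (0.11 and 0.068) and with a stricter count filter (0.20).

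Footprints of eIF3-bound ribosomes show which mRNAs were enriched on ribosomes that carried eIF3B or eIF3E, relative to all ribosomes. Mitochondrially encoded genes, read by ribosomes of another kind, were depleted most: they held 0.963% (0.946 to 0.980) of total footprints, 0.268% (0.259 to 0.276) of eIF3B-bound and 0.299% (0.290 to 0.307) of eIF3E-bound footprints (95% exact Clopper-Pearson intervals). MT-ATP8 had a log2 ratio of −5.75 (−6.39 to −5.22) with eIF3B and −5.74 (−6.34 to −5.24) with eIF3E. Other genes depleted with both were MT-ND2, MT-ATP6, MT-ND4L, MT-ND3, MT-ND5 and MT-ND4, and from the nucleus ATM, a kinase of the DNA damage response, at −2.30 and −1.67, CENPE, a kinetochore motor, at −1.57 and −1.72, and EIF3E itself, at −1.53 and −1.56 (374 counts in total, 147 with eIF3B and 165 with eIF3E). Enriched with both were MAP2K3, a kinase upstream of p38, at 2.49 (1.88 to 3.22) with eIF3B and 1.85 (1.22 to 2.60) with eIF3E, MT2A, at 1.89 and 1.76, and the kinase SRC, at 2.12 and 1.46. NAGPA, CDC42BPG, GTSE1, POLR2L, RNF187 and IGFBP3 followed.

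Of 3575 genes with at least 100 counts in 1 of the 3 libraries, 695 had both intervals above 0 and 595 both below 0. At least 2-fold enrichment with both was seen in 48 genes and depletion in 53, and with a minimum count of 200 in 10 and 27. There are no replicates of these libraries, so no p is given. Noise in the shared total library can put a gene on the same side with both, and how many genes this moves was not simulated. The selective libraries share 1 total library, and their ratios correlated at r = 0.60 across genes where simulated libraries with no effect gave 0.51 from the shared library alone. The covariance was 0.230 against 0.147, and part of the excess of 0.0827 may still come from the shared library.

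Among 34 gene lists, the mitochondrially encoded genes (12 with enough counts) had median log2 ratios of −1.88 and −1.72 with eIF3B and eIF3E. Both lay below all 10000 random lists of the same size, matched on summed counts. Mitosis genes (−0.34 and −0.49), DNA damage genes (−0.79 and −0.46) and heat shock genes (−0.36 and −0.31) lay below the central 95% of random lists with both. Aminoacyl-tRNA synthetases (−0.19 and −0.30), ER translocation genes (−0.13 and −0.30), ER chaperones (0.04 and −0.18) and epithelial junction genes (−0.05 and −0.15) lay below it with eIF3E alone. eIF3 subunits and ribosomal proteins lay inside it (0.16 and 0.12, and 0.03 and 0.12). In simulated data, with genes drawn independently, 2 of 20 unshifted lists fell outside that range.

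**Figure D4:**
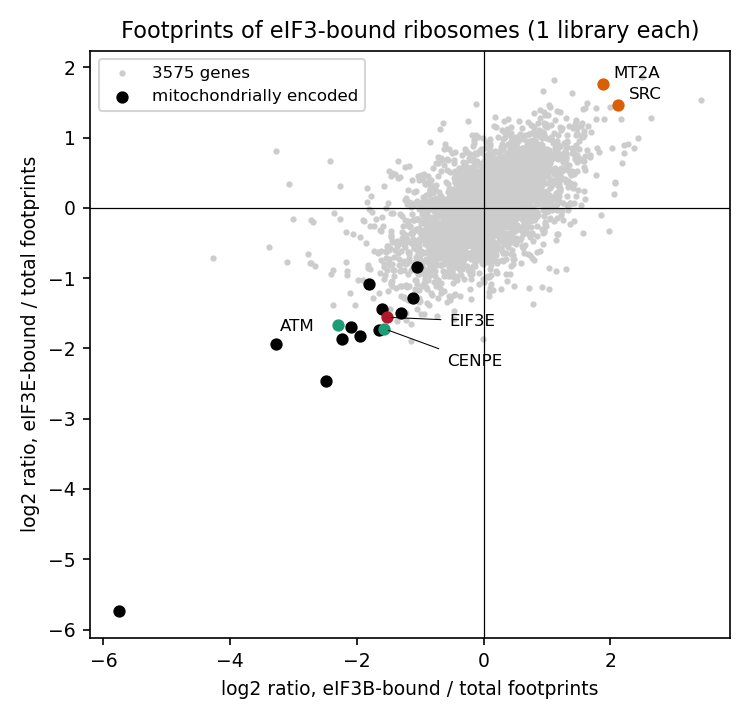
Log2 ratio of eIF3E-bound (y axis) and eIF3B-bound (x axis) over total footprints, one point per gene (3575 genes, 1 library each, no replicates), with mitochondrially encoded genes marked. These lie at the lower left, with medians of −1.88 and −1.72 for eIF3B and eIF3E.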

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

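All comparisons of the total footprint library with the control siRNA libraries were chosen after the values were seen, and the difference was not tested since there is 1 total library. The total footprint library, made from MCF-10A lysate with no siRNA named, stood far from the control siRNA footprint libraries: 461 of 3429 genes compared were at least 4-fold apart. Genes were compared if the total library, or the mean of the control libraries, had at least 100 counts, so a gene high on one side alone could enter. Spearman's rho across genes was 0.485 to 0.536 with the control libraries, where the lowest between control libraries was 0.939. FN1, or fibronectin, was at 6287 CPM, above each control siRNA library (mean 349 ± 86.4 CPM, SD, n = 3). The decoy receptor TNFRSF6B was at 392 CPM against 11.3 ± 2.44 CPM. The linker histone HIST1H1B was at 408 CPM against 22.5 ± 3.01 CPM. These signals stand in a library that the siRNA comparisons do not use.

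The same library was low in genes of squamous differentiation and interferon response. CLDN4, a tight junction claudin, was at 132 CPM against 14440 ± 2564 CPM, and the mucin MUC16 at 4.08 against 973 ± 138 CPM. KLK10 had 0 counts, at least 206-fold lower than the control mean by the floor of 3 counts. Of the fixed lists, 29 of 29 mitosis genes, 10 of 10 replication genes and 8 of 10 mesenchymal genes lay above the range of the 3 control libraries. Below it lay 11 of 11 squamous differentiation genes, 19 of 20 interferon-stimulated genes, 57 of 61 ribosomal protein genes and 12 of 13 mitochondrially encoded genes. The share of all compared genes outside that range was not counted. These counts alone therefore do not set the lists apart from the wide difference between the libraries. The labels give no culture density, passage or batch for this library, and no explanation was tested.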

How the results depend on the processing

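The 7SL term, the restriction to footprint-table genes, all alternatives of the single libraries, the leave-one-out values of the correlation and the eIF3 list without EIF3E were chosen after the data were seen. EIF3E kept its direction and its call in total RNA and footprints under every alternative run, and no called result reversed. Over the alternatives, values of named genes other than EIF3E made 2632 cases in total RNA, 2207 in footprints and 1424 in footprints per mRNA. Calls were lost in 124, 71 and 114 of these and gained in 1, 11 and 10. The sign turned in 5, 0 and 70, all for values called neither before nor after. It turned by more than 1 SE for EIF3M (0.03 with total-count scaling) and EIF3J (0.02 with the 7SL term) in total RNA, and in footprints per mRNA for PSMA7 (−0.05 without control replicate 1) and EIF3J (−0.36 without eIF3e siRNA replicate 3). Called lists kept direction and call in 165, 185 and 39 cases and lost the call in 18, 25 and 9. In total RNA, total-count scaling called 1217 genes lower, and 1 fit over all 12 libraries called 1143 higher and 1166 lower, on 9060 genes in place of 11719. The separate total RNA fit called 1849 higher and 1932 lower among the 9055 genes tested in both assays. The smaller gene set alone therefore does not account for the fewer calls. In footprints the fit over all 12 libraries called 1328 higher and 1295 lower, against 926 and 781. It gives each gene 1 spread for both assays, and the test of footprints per mRNA rests on it. The cause of these shifts was not tested. With estimated inter-gene correlation the lists called higher and lower were 0 and 0 in total RNA, 0 and 1 in footprints and 0 and 0 in footprints per mRNA. Leaving out each library gave 1663 to 2166 genes higher and 1722 to 2284 lower in total RNA, and 668 to 879 and 546 to 821 in footprints.

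Footprints per mRNA (7 higher and 15 lower) moved as well: 13 and 26 with total-count scaling, 21 higher with no filter, 18 and 28 with a minimum count of 50, 76 and 66 with the DESeq2 Wald test, 26 higher with TMM over all 12 libraries, and 13 higher with limma-voom. Replicate number as a block gave 2 and 4, and treatment and number as a culture block 82 and 64. The 7SL term gave 0 and 0, with 0 lists higher (792 genes at an unadjusted p under 0.05). Leaving out replicates gave 0 to 7 higher and 0 to 14 lower, with 1 to 2 lists higher and 2 to 4 lower, and at 0 calls 951 to 996 genes at an unadjusted p under 0.05. The cause was not tested. Correlations of residuals of control and eIF3e siRNA libraries with equal numbers were −0.01, 0.19 and 0.30 in total RNA and −0.00, 0.03 and 0.00 in footprints. Those of total RNA with footprint libraries of equal number were 0.134, 0.0015 and 0.119 in control and 0.038, 0.043 and 0.042 after eIF3e siRNA, all positive and highest for the equal number in all but control number 2. This is a hint of pairing from the data, not the design. Not every pair passed 0.1. The labels do not say that equal numbers share a culture, so the main fits have no block. With replicate number as a block 2384 genes rose and 2222 fell in total RNA, and 901 and 775 in footprints.

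Across genes, r was 0.80, rho 0.76 and the slope 1.105 with the stricter filter. Without one treatment and number r was 0.56 to 0.64, rho 0.56 to 0.65 and the slope 1.42 to 1.74. In the single libraries a minimum count of 200 gave 10 genes 2-fold higher and 27 lower with both, from fewer genes, and medians of −1.73 and −1.60 for the mitochondrially encoded genes. Of simulated 2-fold changes 38.8% were recovered in footprints and 77.6% in total RNA. In footprints per mRNA 38.8% were recovered, with both assays drawn with 1 spread. Footprints had both fewer counts and a larger replicate variation (0.245 against 0.155), and depth was not varied alone.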

Other observations

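The tests of blood, fibroblast or endothelial cells, of the siRNA sequence and of a common mitochondrial loss were chosen only after the result was seen, as were the 7SL term and total-count scaling with libraries left out. Several fixed lists did not pass as lists yet held genes that moved clearly. Of the p53 targets 3 of 23 tested members rose and 9 fell (3 and 9 adjusted over the list alone) in total RNA, where MDM2 (−0.74 ± 0.10), CCNG1 (−0.87 ± 0.10) and ZMAT3 (−0.80 ± 0.10) fell and BAX rose (1.01 ± 0.14). In footprints 1 of 22 tested members rose and 4 fell (3 and 5 adjusted over the list alone), with MDM2 at −1.26 ± 0.12 and the cell cycle inhibitor CDKN1A at −0.99 ± 0.15 (camera adjusted p = 0.28 in total RNA and 0.19 in footprints). Of the basal epithelial markers 7 of 17 tested members rose and 8 fell (7 and 8 adjusted over the list alone) in footprints: the keratins KRT14 (−0.97 ± 0.11) and KRT15 (−1.10 ± 0.13) fell, and the laminin LAMA3 (0.77 ± 0.11) and the receptor EGFR (0.82 ± 0.11) rose (camera adjusted p = 0.36). Of the hypoxia genes 10 of 24 tested members rose and 4 fell (11 and 6 adjusted over the list alone) in total RNA, with adrenomedullin, ADM, at 1.56 ± 0.11 and ANGPTL4 at 1.08 ± 0.11; the median was −0.04, the test pointed up and did not pass (camera adjusted p = 0.36). Of the tricarboxylic acid cycle genes 6 of 22 tested members rose and 3 fell (9 and 4 adjusted over the list alone) in footprints, with OGDH at 0.81 ± 0.13 and the cytosolic IDH1 at −1.09 ± 0.16 (camera adjusted p = 0.075).

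Of the ATF4 and stress response genes 7 of 26 tested members rose and 7 fell (7 and 7 adjusted over the list alone) in total RNA, with CHAC1, a glutathione-degrading enzyme, at −1.49 ± 0.23 (camera adjusted p = 0.75). Of the NF-kB genes 4 of 19 tested members rose and 5 fell (5 and 5 adjusted over the list alone) in footprints, with SOD2 at 1.13 ± 0.12 and IL1B at −0.98 ± 0.14 (camera adjusted p = 0.85). Of the DNA damage genes 8 of 25 tested members rose and 3 fell (10 and 3 adjusted over the list alone) in total RNA, with XRCC2 at 1.88 ± 0.32 and BRCA2 at 1.39 ± 0.26 (camera adjusted p = 0.18). Of the mitosis genes in footprints 2 of 35 tested members rose and 5 fell (3 and 6 adjusted over the list alone), at camera adjusted p = 0.76. In total RNA 5 of 36 tested mitosis genes rose and 1 fell (5 and 1 adjusted over the list alone), with CCNB1 at 0.71 ± 0.14 (camera adjusted p = 0.28). Of the cholesterol genes 6 of 24 tested members rose and 2 fell (6 and 2 adjusted over the list alone), with LSS at 0.80 ± 0.10 (camera adjusted p = 0.49), and of the aminoacyl-tRNA synthetases 4 of 20 tested members rose and 3 fell (4 and 3 adjusted over the list alone), with VARS at 0.87 ± 0.11 and QARS at −0.72 ± 0.10 (camera adjusted p = 0.66). Of the ER translocation genes 7 of 31 tested members rose and 4 fell (7 and 4 adjusted over the list alone), at camera adjusted p = 0.75, of the proteasome subunits 2 of 31 tested members rose and 3 fell (2 and 3 adjusted over the list alone), at camera adjusted p = 0.75 and of the nonsense-mediated decay factors 3 of 14 tested members rose and 0 fell (1 and 0 adjusted over the list alone), at camera adjusted p = 0.42. The median, mean and test of a list differed in sign in 8 cases, none of them called (0): ATF4, NF-kB and hypoxia genes in total RNA, NF-kB genes in footprints, and initiation factors, ER translocation genes, ER chaperones and p53 targets in footprints per mRNA.

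By list median, ribosomal protein mRNAs were lower in total RNA (−0.45), with more footprints per mRNA (0.27). Called members were 31 of 79 lower and 1 higher in total RNA, and 1 of 68 higher and 0 lower in footprints per mRNA. Neither camera call held with an estimated correlation (adjusted p = 0.71 and 0.77), and fry called neither. By the rule set beforehand, one total RNA library is argued against as the source. With each library left out in turn the medians ran from −0.57 to −0.34, all below its bound of −0.3. The explanation stays open only on checks outside that rule. The highest median cleared the bound by less than the spread of 0.0987 (SD) between these medians. With total-count scaling the median was −0.28 with all libraries and −0.37 to −0.21 with each left out, above that bound without control library 1 or 2 or eIF3e siRNA library 1 or 3. The list was called in each of these fits. The 7SL share of the libraries stays open: with it as a term, added after the data were seen, the median was −0.27 against −0.45 without it. This lay between the bounds of that check. With that term 19 genes were still lower and the list was still called at the preset correlation (camera adjusted p = 0.0013). An estimated correlation was not tried with the term. In footprints per mRNA the median then went from 0.27 to 0.08 and the list was no longer called, with a median SE of 0.164 against 0.163 in total RNA. A candidate explanation, that lost ribosomal protein mRNA is offset in part by more ribosomes on each, cannot be told apart from the 7SL difference.

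Interferon-stimulated genes were higher after eIF3e siRNA, by a median of 0.90 in total RNA and 0.42 in footprints (0.27 without eIF3e siRNA library 2). Blood, fibroblast or endothelial cells as the source were checked with 19 transcripts fixed as a list. The list mixes these kinds of cells, so its median would stay low with cells of 1 kind and cannot decide. It was 0.148 CPM in eIF3e siRNA total RNA, below the limit of 0.704 CPM that 3 counts give. Of the 19 transcripts 13 lay at or below that limit. Of the others DCN rose from 25.2 to 47.0 CPM and CD14 from 48.4 to 79.8 CPM, both also called in footprints, and COL1A1 was at 6.24 and 7.84 CPM. PDGFRB (0.986 CPM, against 0.263 CPM in control), CDH5 (0.832 against 1.33 CPM) and HBB (1.21 against 11.1 CPM) were near the limit. DCN rose without the fibroblast collagens COL1A2 and COL3A1 (0 and 2 counts over the 3 eIF3e siRNA libraries), and CD14 without LYZ and PTPRC (1 count each). The endothelial PECAM1 and VWF had 2 and 1 counts. These low markers go against such cells, while DCN, CD14, COL1A1 and PDGFRB, all higher after eIF3e siRNA, go the other way. The values do not decide. A response to the siRNA sequence itself, and not to loss of eIF3e, could also raise these genes: the labels name 1 eIF3e siRNA treatment, so the explanations, response to the siRNA itself or to the loss, cannot be told apart. A second siRNA or a rescue would decide.

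By list median (−0.31), mitochondrially encoded mRNAs had fewer footprints per mRNA, with 3 of 13 called lower and 0 higher. The camera call did not hold with an estimated correlation (adjusted p = 0.77), and fry did not call the list. Whether the lower median is one common loss stays open: the changes in footprints per mRNA of the 13 genes ran from −1.26 to 0.43. Their heterogeneity statistic was 5.90 per degree of freedom, where about 1 would be seen with one common change. Without MT-ND6 it was 5.00. Another check left out 6 genes whose counts are uncertain. MT-ATP6, MT-ATP8, MT-ND4 and MT-ND4L overlap one another in pairs, while MT-ND5 and MT-ND6 only adjoin on opposite strands. Without these 6 the statistic was 2.81 for the remaining 7, and 1.52 when eIF3e siRNA replicate 3 was left out too, below the bound of 2. It was not computed with the overlapping genes alone left out. The 7SL share stays open: with it as a term the median was −0.25 against −0.31, below the bound of −0.2 but by less than the spread of 0.105 (SD) between medians with one replicate left out, a margin added after the value was seen. With that term the list was still called at the preset correlation (camera adjusted p = 0.00056), and an estimated correlation was not tried. Those medians ran from −0.39 to −0.12. No biological explanation was tested.

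The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes as the real split: 4399 genes in total RNA, 1707 in footprints and 22 in footprints per mRNA, where the highest of the other splits gave 0 in edgeR at the same threshold. At an unadjusted p under 0.05 the highest of the others gave 516, 261 and 177 genes, below the 586, 461 and 453 expected by chance. Each other split mixes control and eIF3e siRNA libraries, so the siRNA effect enters the spread within its groups and lowers its calls. The 0 is therefore no measure of what chance would give.

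The ratios of eIF3-bound to total footprints had Pearson correlations of −0.05 to 0.13 with the changes after eIF3e siRNA. Across 3561 genes the Pearson correlation with the change in footprints per mRNA was −0.05 with eIF3B and −0.04 with eIF3E, and across 3569 genes that with the footprint change was 0.07 and 0.10. Across 3564 genes that with the mRNA change was 0.11 and 0.13 (Spearman's rho 0.12 and 0.14). These correlations are across genes, which are not independent replicates, and the total footprint library differed from the control siRNA libraries in the levels given above. Some genes differed between the selective libraries themselves: PYCR1, a proline synthesis enzyme, had 6 against 126 counts with eIF3B and eIF3E, IPO11 6 against 87 counts and the nucleoporin SEH1L 9 against 115 counts, while TIAM1 had 123 against 28 counts and PPID 117 against 29 counts. These were named after their values were seen, with no replicate.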
